A study of Mus musculus with 6 samples.

How the data were processed

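RNA was taken from liver endothelial cells that were sorted by flow cytometry from mice on a control-iron or a high-iron diet, 3 biological replicates per group. RNA was isolated with a column kit for small samples, and libraries were made with a low-input cDNA kit, per the labels' protocols; that kit does not mark the strand of a transcript, so reads of a gene and an antisense partner cannot be told apart. The submitters' processing notes name STAR, HTSeq, edgeR and the mouse build mm10, with no versions or roles; the annotation release and counting options are not given in the sources used here.

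The authors deposited 2 tables of 39179 genes by 6 libraries, each with an identifier, a symbol and a gene length. The first holds a normalized signal named CPM, which the authors made by dividing the reads of each gene by a scaled library size. Each of its 114253 values above 0 is a whole multiple of the library's step within 0.001 read (100%), so the reads per gene could be recovered. Scaling factors recomputed from the recovered reads with edgeR's TMM method matched the deposited ones with a relative difference of at most 6.7e-16. For that reason the column totals differ and run from 964515 to 1025619. The second deposited table holds RPKM values, which equal 1000 × CPM / gene length with a largest difference of 8.0e-11, so it carries no further measurement. The deposited Length column is the gene length in bases. No column of per-sample values was left unused.

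Depth was 12963510 to 21663543 recovered reads in genes per library. A floor of 3 reads corresponds to between 0.139 CPM in the deepest and 0.231 CPM in the shallowest library, and covers counting error only. Libraries of a group differed by a chi-square per degree of freedom of 16.0 to 76.2 over genes, far above sampling noise, so none was treated as a duplicate. No sequencing batch or date is given in the labels.

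The design was fixed before the data were examined. The main test was limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with group as the sole term, an intensity trend in the variance and two-sided moderated statistics with 4 residual degrees of freedom. Genes with a CPM of at least 1 in at least 3 of the 6 libraries were tested, 12980 in all, with Benjamini-Hochberg adjustment and a threshold of 0.05. Because reads could be recovered, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 were run on them as alternatives. Of the genes tested, edgeR called 112 (93 higher, 19 lower) and DESeq2 424 (328 higher, 96 lower), of which 109 and 133 were among the 133 limma calls. DESeq2 gave no adjusted p for 2 genes.

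There were 37 gene lists, on BMP and iron biology, oxidative and other stress, endothelial subtypes and pathways, RNA quality, and other liver and blood cell types, each written before the data were examined. Of 711 listed genes, 709 were found in the table, 7 of them under another symbol through the Ensembl identifier. Lists with at least 3 tested genes were tested with limma's camera with a preset correlation of 0.01, two-sided, adjusted over the lists. Camera with an estimated correlation and fry were run beside it; fry called 4 lists, and 17 in its test of change in either direction. Counts adjusted over the list alone use the same p-values with adjustment inside each list.

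Named genes followed a rule: the 12 largest rises and falls among called genes with a mean CPM of at least 5, no overlap between groups and an established symbol; 26 preset genes, of which 25 were tested; up to 4 members of each list with the smallest p, or the 2 most abundant where none passed; and called members of biology lists. A further 8 genes were chosen after their values were seen and are marked so. Gene positions and overlaps come from GENCODE M21 on GRCm38, which is mm10; 37607 of the 39179 identifiers are in it. Near-identical copies of the named genes were searched among its transcripts with BLAST+ 2.17.0, counting matches of at least 95% identity over at least 50% of the transcript.

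The procedure was tested on simulated reads drawn with the gene means, dispersions and sizes of these libraries, with known genes changed. In the simulated high_iron against control_iron comparison of 12771 genes, limma recovered 45.4% of 97 genes changed 2-fold and 87.4% of 95 genes changed 4-fold, with 6 false calls among 133. Figures for edgeR were 45.4% and 85.3% with 5 false calls among 130, and for DESeq2 58.8% and 91.6% with 24 false calls among 168. In a simulation of the list test on 12766 genes, a list of 20 genes raised 2-fold was called by camera with the preset correlation, and 0 of 20 unchanged lists were. Genes were drawn independently in both simulations, with the same dispersion in both groups. List genes in these data moved together (estimated correlation 0.30 for NRF2 targets and 0.59 for macrophage markers). The list simulation therefore cannot tell how often such lists are called falsely.

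Alternatives were pseudocounts of 0.1 and 0.5, no filter and a CPM of at least 5, median-of-ratios and quantile scaling, the RPKM table, no intensity trend, the replicate number as a block, each library left out in turn, edgeR, DESeq2 and the estimated correlation. A macrophage marker score as a covariate, the mean log2(CPM + 1) of 16 markers without Hmox1 and Slc40a1, and leaving out genes that stand in more than 1 list were added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.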

Results

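Gene expression was measured by RNA sequencing in endothelial cells sorted from the livers of wild-type 129S6/SvEvTac male mice. Mice received a purified diet from the age of 3 weeks and were sampled after 4 weeks on it, at 7 weeks. In the control_iron group the diet held 37 ppm iron as ferric citrate, and in the high_iron group it held 10000 ppm carbonyl iron, a load that drives iron into the liver. Each group had 3 biological replicates, 6 libraries in all. The sort kept cells that carried the endothelial surface proteins CD31 and CD146 and lacked CD45, lineage markers, MHC class II and CD64, a gate that removes most blood-derived cells. Reads assigned to genes numbered 18566380, 21663543 and 18008668 in control_iron replicates 1 to 3, and 19265165, 17295321 and 12963510 in high_iron replicates 1 to 3. Levels are given as CPM, the reads of a gene over a scaled library size. Across the genes tested, which are not independent replicates, log2(CPM + 1) values of library pairs correlated with r between 0.964 and 0.988 within a group and between 0.951 and 0.981 across groups. Control_iron replicate 2 correlated more closely with high_iron replicates 2 and 3 (0.978 and 0.981) than with control_iron replicates 1 and 3 (0.971 and 0.977). The control_iron libraries were spread more widely than the high_iron libraries. On the first principal component (41.3% of the variance) control_iron replicates 1 to 3 lay at -13.2, -5.06 and -41.4. High_iron replicates 1 to 3 lay at 7.44, 31.2 and 21.1, so the groups did not overlap on it.

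The comparison asked which transcripts of liver endothelial cells differ after dietary iron loading. Bmp6, the ligand through which liver endothelial cells signal iron load to hepatocytes, rose from 127 ± 32.8 to 766 ± 136 CPM (SD, n = 3 per group), a 6.04-fold change. Of 33 tested target genes of the transcription factor NRF2, 16 rose beside it (10 without high_iron replicate 3), among them Hmox1, Nqo1, Gclc, Gclm, Txnrd1 and Srxn1. The iron exporter gene Slc40a1 rose too. Macrophage markers, a list that also holds Hmox1 and Slc40a1, were higher in the same libraries. Its other 16 genes had a median log2 fold change of 1.37. Of 12980 genes tested, 133 changed at an adjusted p under 0.05, 108 of them higher and 25 lower on the high-iron diet, and 92 changed by at least 2-fold. Libraries of the 2 groups did not overlap for 17.9% of genes tested, where chance gives 10%. The median log2 fold change over all genes tested was -0.003. Folds are on the log2(CPM + 1) scale, which understates the change of low genes, and adjusted p-values come from limma with Benjamini-Hochberg adjustment.

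**Figure D1:**
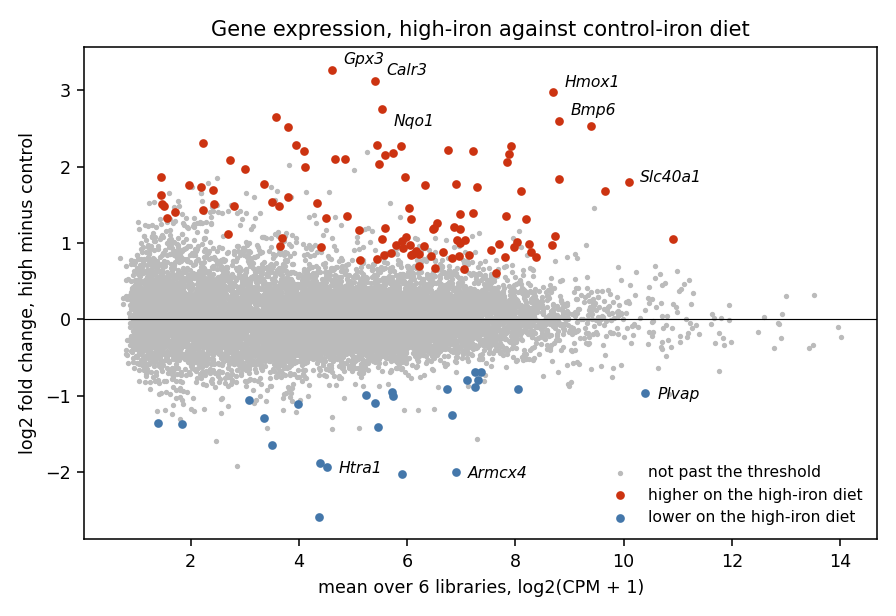
Log2 fold change (high_iron minus control_iron) of the 12980 genes tested against their mean log2(CPM + 1) over 6 libraries. Red points are the 108 genes higher and blue points the 25 genes lower on the high-iron diet at an adjusted p under 0.05, and Bmp6, Hmox1 and Slc40a1 stand out among the abundant genes.

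Among well-expressed named genes, the 12 largest rises were those of Gpx3, Calr3, Hmox1, Nqo1, Pir, Bmp6, Akr1b8, Ccdc150, Nrxn2, Csf1r, Gstp1 and Clec4f, with log2 fold changes from 3.27 down to 2.27. Gpx3, the secreted glutathione peroxidase, rose from 3.89 ± 2.61 to 42.8 ± 8.64 CPM (SD, n = 3). Akr1b8, an aldo-keto reductase, was the most abundant of them and rose from 199 ± 36.8 to 1152 ± 125 CPM. Gstp1 shares 86.1% of its transcript with Gstp2 at 95% identity or more, so its reads may be split between the pair. Csf1r and Clec4f, both known from macrophages, are described with the other cell types. The 12 largest falls were those of Tspan13, Armcx4, Htra1, Ackr3, Pdzd2, Il13ra2, Tenm1, Tnfsf10, Fabp5, Col27a1, Susd4 and Ddah1, with log2 fold changes from -2.02 to -1.01. Htra1, a secreted serine protease, fell from 35.4 ± 5.37 to 8.52 ± 1.80 CPM. Ackr3, a scavenger receptor for the chemokine CXCL12, fell from 32.5 ± 20.3 to 7.22 ± 1.76 CPM, and Il13ra2, the decoy receptor for interleukin 13, from 62.5 ± 0.402 to 23.1 ± 4.34 CPM. With 1 library left out, 10 of the 12 rises and 4 of the 12 falls, those of Tspan13, Armcx4, Htra1 and Il13ra2, passed the threshold in each of the 6 fits. Clec4f failed it without control_iron replicate 3 and without each high_iron library (adjusted p up to 0.18), and Csf1r without high_iron replicate 3 (adjusted p = 0.051). The other 8 falls failed it without at least 1 library, with a highest adjusted p between 0.12 and 0.22 per gene: 10 of the 12 falls passed without control_iron replicate 1, 5 without control_iron replicate 2, 4 without control_iron replicate 3, 6 without high_iron replicate 1, and 4 each without high_iron replicates 2 and 3.

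**Figure D2:**
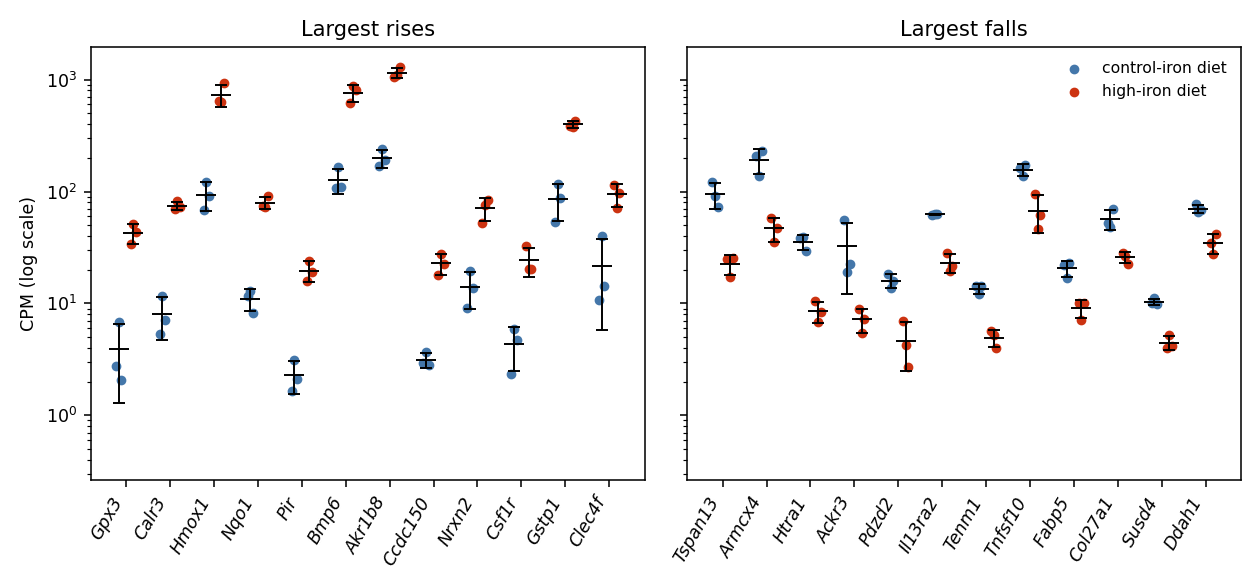
CPM per library (log axis) of the 12 largest rises, left, and the 12 largest falls, right, among named genes. Blue points are the 3 control_iron and red points the 3 high_iron libraries, with bars for the mean and SD; for Bmp6, control_iron libraries lie between 107 and 165 CPM and high_iron libraries between 613 and 875 CPM.

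Of 33 tested target genes of NRF2, the transcription factor of the oxidative and electrophile response, 16 rose and none fell, and 31 had a positive log2 fold change with a median of 0.99. Adjusted over the list alone, 27 rose. Hmox1, heme oxygenase, rose from 94.0 ± 27.3 to 736 ± 167 CPM (SD, n = 3), and Nqo1, a quinone reductase, from 11.0 ± 2.44 to 79.3 ± 10.1 CPM. Gclc and Gclm, the subunits of the enzyme that limits glutathione synthesis, rose by 2.16 ± 0.17 and 2.06 ± 0.15 (log2 fold change ± SE, adjusted p = 3.3e-04 each). Txnrd1, thioredoxin reductase, rose by 2.22 ± 0.17, Srxn1, sulfiredoxin, by 2.18 ± 0.20 and Aox1, an aldehyde oxidase, by 2.03 ± 0.16. Gsr, glutathione reductase, and G6pdx and Pgd of the pentose phosphate pathway rose by 1.39, 1.35 and 1.26; the exons of G6pdx overlap Ikbkg over 13.6% of their length. Slc7a11, the cystine transporter gene, was listed at under 0.12 CPM in every library, below the level of 3 reads, and was not tested. The list was called by camera with a preset correlation (adjusted p = 1.0e-33) and was not called with an estimated one (adjusted p = 0.24 with an estimated correlation). Without high_iron replicate 3, 10 of the 33 rose, and G6pdx and Pgd missed the threshold (adjusted p = 0.077 and 0.064). Macrophage markers were higher in the same libraries, with a median log2 fold change of 1.37 over 16 genes, a list that leaves out Hmox1 and Slc40a1.

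Bmp6 rose by 2.59 ± 0.20 (log2 fold change ± SE, adjusted p = 3.3e-04), and it was the one gene of 13 tested BMP ligands and receptors that passed the threshold. The gene (ENSMUSG00000039004) lies on chromosome 13, from 38345107 to 38500302 on the plus strand of GRCm38 (mm10), with 9 merged exons in GENCODE M21, 5.74% of whose length overlaps Txndc5 on the opposite strand. Its adjusted p stayed at or below 0.0056 with any 1 library left out, and with a macrophage marker score as a covariate its log2 fold change was 2.49 ± 0.42 (± SE) and no longer passed (adjusted p = 0.43). Bmp2, the other ligand known to act on hepatocytes in iron signalling, was more abundant, at 2176 ± 221 CPM in control_iron and 2775 ± 393 CPM in high_iron libraries, and did not pass the threshold (log2 fold change 0.35, adjusted p = 0.46). Adjusted over the list alone, 1 gene rose and 2 fell. The median of the list was -0.04 and its mean 0.13, and camera gave an upward direction with an adjusted p of 0.90. Among 12 tested targets of BMP-SMAD signalling, Id2 rose by 1.09 ± 0.15 (adjusted p = 0.011; 0.10 without high_iron replicate 3), and 3 passed when adjusted over the list alone. Id1, Id3, Smad6 and Smad7, which respond to BMP signals in many cells, did not pass the threshold, with log2 fold changes of -0.57 ± 0.40, -0.40 ± 0.17, -0.24 ± 0.15 and 0.19 ± 0.17 (± SE). Atoh8 had a log2 fold change of 0.87 ± 0.25 (adjusted p = 0.17), and Hamp, the hepcidin gene expressed mainly in hepatocytes, was at 7.21 ± 5.34 and 19.6 ± 7.49 CPM (adjusted p = 0.32). The BMP-SMAD target list was not called by camera (adjusted p = 0.19). Fry's test of change in either direction called it (adjusted p = 0.0020), and also the list of BMP ligands and receptors (adjusted p = 0.0032).

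Of 26 tested genes of iron uptake, storage and export, 4 rose and none fell. Slc40a1, ferroportin, which exports iron from cells and lies on chromosome 1 from 45908068 to 45926523 on the minus strand, rose from 484 ± 33.4 to 1693 ± 299 CPM (SD, n = 3; adjusted p = 8.8e-04). Ftl1, ferritin light chain, rose from 200 ± 63.9 to 690 ± 69.9 CPM, Slc48a1, a heme transporter, rose from 126 ± 11.5 to 325 ± 65.5 CPM, and Hmox1 is the fourth. Ftl1 has pseudogenes nearly identical to it, so its reads are uncertain. Without high_iron replicate 3, Ftl1 and Slc48a1 missed the threshold (adjusted p = 0.051 each). Tfrc, the transferrin receptor whose mRNA is held low in iron-rich cells, was at 1.72 ± 0.165 and 3.09 ± 1.06 CPM (adjusted p = 0.42), and Fth1, ferritin heavy chain, had a log2 fold change of 0.45 (adjusted p = 0.44). Adjusted over the list alone, 7 rose. The list was called upward (adjusted p = 2.0e-05 with the preset correlation, adjusted p = 0.24 with an estimated correlation). Hmox1 and Slc40a1 are also on the list of Kupffer cell and macrophage markers, whose other 16 genes had a median log2 fold change of 1.37 in the same libraries. Of 6 metal-response genes none passed the limma test, while 2 passed adjusted over the list alone, 2 had an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 1. Metallothioneins Mt1 and Mt2 had log2 fold changes of 1.45 ± 0.34 (adjusted p = 0.091) and 1.06 ± 0.30 (adjusted p = 0.17). Another gene model overlaps 73.5% of the exon length of Mt2. The metal-response list was not called (adjusted p = 0.12; 0.0068 without control_iron replicate 3, where 2 genes passed).

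Genes that mark sinusoidal endothelium did not pass the threshold: 0 of 20 by limma, of which 3 had an unadjusted p under 0.05, with 0 called by edgeR and 1 by DESeq2. The scavenger receptor gene Stab2 was at 3687 ± 654 and 3222 ± 362 CPM (SD, n = 3), and Lyve1, the hyaluronan receptor, had a log2 fold change of 0.64 ± 0.16 (adjusted p = 0.12). Of 12 pericentral genes Fabp4 fell, by 0.91 on the log2 scale, of 18 capillary and large-vessel genes Plvap fell, by 0.97 on the log2 scale from 1798 ± 383 to 907 ± 62.0 CPM, and of 14 periportal genes Clu rose by 1.21. Fabp4 missed the threshold without control_iron replicate 3 and without each high_iron library (adjusted p up to 0.19), Clu without control_iron replicate 3 and high_iron replicates 2 and 3 (up to 0.19), and Plvap in every fit but that without control_iron replicate 3 (up to 0.23). Adjusted over the list alone, 0 sinusoidal identity genes passed, 1 pericentral gene rose and 1 fell, 1 capillary gene rose and 2 fell, and 1 periportal gene rose and 1 fell. Camera called none of these 4 lists (adjusted p = 0.60, 0.38, 0.76 and 0.76), though the pericentral list passed without control_iron replicate 3 (0.016). Camera tests a shift in 1 direction. Fry's test of change in either direction called the sinusoidal identity list (adjusted p = 0.0032). It did not call the pericentral, capillary and periportal lists (adjusted p = 0.073, 0.057 and 0.055). The secreted factors Wnt2 and Rspo3, which pericentral endothelium gives to hepatocytes, had log2 fold changes of 0.10 ± 0.23 and -0.59 ± 0.23 and did not pass. Of 17 angiocrine factors, Bmp6 and Hgf rose, and adjusted over the list alone 3 rose and 1 fell. Hgf, hepatocyte growth factor, rose from 24.8 ± 2.48 to 97.4 ± 35.2 CPM, and missed the threshold without control_iron replicate 3 and without high_iron replicates 1 and 2 (adjusted p up to 0.071). The angiocrine list was not called by camera (adjusted p = 0.096; 0.016 without high_iron replicate 3 and 0.0070 with edgeR) and was called by fry (adjusted p = 0.039), and Hgf is also on the list of stellate cell genes.

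**Figure D3:**
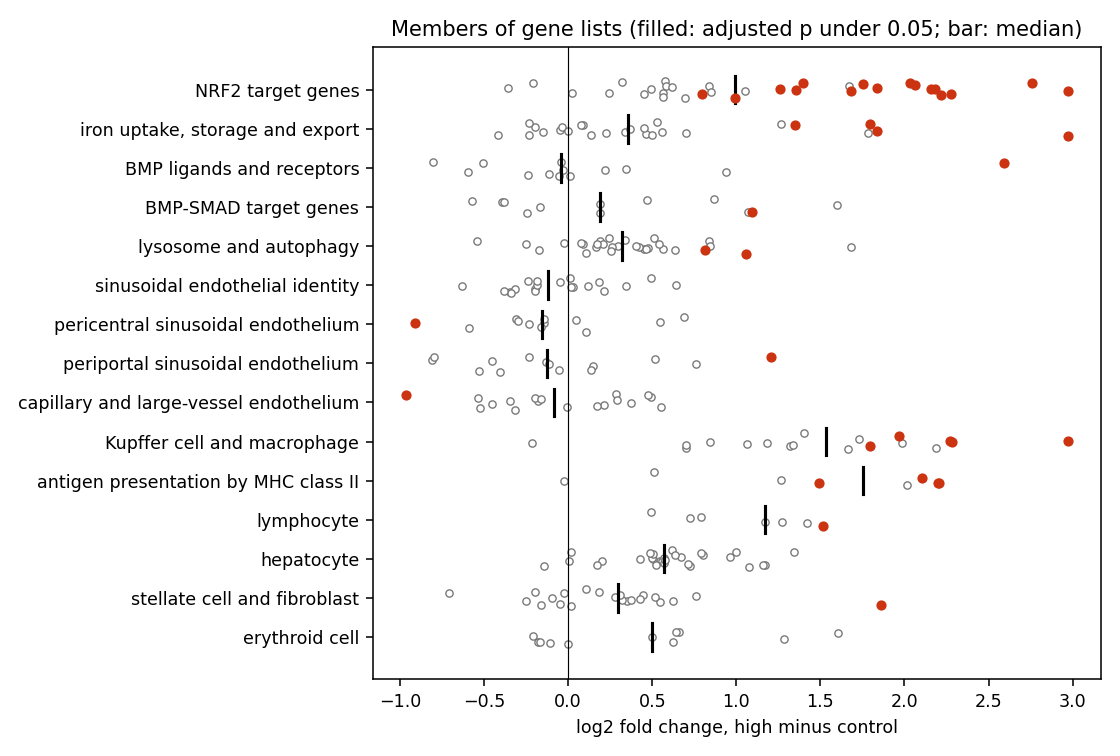
Log2 fold change (high_iron minus control_iron) of each tested member of 15 gene lists, with a bar at each list's median. Filled red points passed an adjusted p of 0.05: 16 of 33 NRF2 target genes, 4 of 26 iron genes, 5 of 18 macrophage markers and 0 of 29 hepatocyte markers.

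Markers of cells that the gate should leave out were also higher on the high-iron diet. Of 18 Kupffer cell and macrophage genes, 5 rose (Hmox1, Slc40a1, Csf1r, Marco and Clec4f), 17 had a positive log2 fold change, and 16 rose adjusted over the list alone. Clec4f, a lectin of Kupffer cells, rose from 21.6 ± 15.9 to 94.7 ± 22.0 CPM (SD, n = 3), and Csf1r, the receptor for the growth factor of macrophages, from 4.32 ± 1.81 to 24.3 ± 7.19 CPM; exons of Csf1r overlap Hmgxb3 on the opposite strand over 15.1% of their length. Of 8 genes of MHC class II presentation, H2-Aa, H2-Ab1, Cd74 and H2-DMb1 rose, and 6 rose adjusted over the list alone; H2-DMb1 is nearly identical to H2-DMb2. Cd74 was at 48.9 ± 16.7 and 246 ± 149 CPM. Of 22 listed lymphocyte genes 7 were tested. Of these 7 Ighm rose, a call lost in each of the 6 fits with 1 library left out (adjusted p up to 0.24), and 6 rose adjusted over the list alone. Ptprc, which encodes CD45, had a log2 fold change of 1.27 ± 0.35 (adjusted p = 0.15). All 3 lists were called upward by camera with the preset correlation (adjusted p = 1.4e-17, 3.5e-08 and 1.8e-06), and none with an estimated one (adjusted p = 0.29 with an estimated correlation for each). The macrophage count was 8 without control_iron replicate 2, 3 without control_iron replicate 3 or high_iron replicates 1 or 2, and 2 without high_iron replicate 3. The MHC class II count was 1 without control_iron replicate 2 or high_iron replicate 1, and 0 without control_iron replicate 3 or high_iron replicate 3.

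Hepatocyte markers were higher in 28 of 29 cases with a median log2 fold change of 0.57, and none passed the limma test (2 did without control_iron replicate 2), while 6 had an unadjusted p under 0.05, 3 rose adjusted over the list alone, and edgeR called 0 and DESeq2 3. Albumin mRNA (Alb) was at 175 ± 104 CPM in control_iron and 227 ± 38.0 CPM in high_iron libraries. The hepatocyte list was called by camera (adjusted p = 5.8e-06; 0.35 without control_iron replicate 1), and not with an estimated correlation (adjusted p = 0.67 with an estimated correlation). Of 22 stellate cell and fibroblast genes Hgf alone rose, also adjusted over the list alone, with a list median of 0.29 (adjusted p = 0.31; 0.0016 without control_iron replicate 2 and 0.0010 without high_iron replicate 1). No member of the erythroid (11 tested of 14 listed), platelet (8 of 11), cholangiocyte (3 of 12) or neutrophil and monocyte (3 of 17) lists passed. Their medians were 0.50, 0.63, 0.65 and 0.37, and adjusted over the list alone 4 platelet genes rose. Over these 4 lists and the hepatocyte list, 13 of 54 genes had an unadjusted p under 0.05, edgeR called 0 and DESeq2 4. With the replicate number as a block, 9 hepatocyte, 3 erythroid and 2 platelet genes passed. Camera called the platelet list (adjusted p = 0.012, adjusted p = 0.29 with an estimated correlation; 0.11 without control_iron replicate 1). It did not call the erythroid cell list (adjusted p = 0.20; 0.015 without control_iron replicate 2 and 3.0e-04 without high_iron replicate 3).

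Lysosome and autophagy genes were higher in 26 of 30 cases, with a median log2 fold change of 0.32. Ctsd, the protease cathepsin D, rose from 1248 ± 163 to 2601 ± 407 CPM (SD, n = 3), and Hexa, a subunit of hexosaminidase, from 161 ± 20.1 to 285 ± 43.6 CPM. An overlapping gene model on the same strand covers 34.4% of the exon length of Ctsd, and Tmem202 12.8% of that of Hexa. These 2 of the 30 passed the threshold, and 12 rose adjusted over the list alone. Of the 2 calls, 1 was left without control_iron replicate 2 or high_iron replicate 1, and 0 without control_iron replicate 3 or high_iron replicates 2 or 3. The list was called upward with the preset correlation (adjusted p = 2.6e-08, adjusted p = 0.29 with an estimated correlation), in libraries where the macrophage markers, whose cells are rich in lysosomes, had a median of 1.37.

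The count of 133 genes was 88 without control_iron replicate 2, 53 without control_iron replicate 3, 55, 43 and 27 without high_iron replicates 1, 2 and 3, and 183 without control_iron replicate 1; it was 34 with no filter on low values, 83 on RPKM values, 74 with no intensity trend, 424 with DESeq2 and 0 with a macrophage marker score as a covariate, a setting chosen after the data were seen, which left 874 genes at an unadjusted p under 0.05. A permutation test of a single gene with 3 libraries against 3 cannot give an exact two-sided p below 0.1, so the calls rest on limma's pooled estimate of the spread. Of the 37 lists, camera called 11 upward and 0 downward, and none with an estimated correlation, where 5 had an unadjusted p under 0.05. Fry called 4, those of NRF2 targets, iron genes, lysosome and autophagy genes and angiocrine factors. Its test of change in either direction called 17. Among these, camera had not called sinusoidal identity, BMP ligands and receptors, BMP-SMAD targets, angiocrine factors, hypoxia, ferroptosis, integrated stress response and immediate-early genes.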

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

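The macrophage covariate and the removal of genes in more than 1 list were chosen after the data were seen; the other settings were not. All 67 named genes that passed the threshold kept their direction in each alternative that gave them a value, and 24 of them passed in all 6 fits with 1 library left out. Of 2792 recomputed values of named genes, 2410 stayed on their side of the threshold, 331 fell below it, 51 rose past it and 0 called values changed sign; of 662 list results, 619 stayed, 21 lost and 22 gained the call. Other pseudocounts, the stricter filter, both other scalings and edgeR gave between 112 and 136 genes and 9 to 11 lists, and leaving out genes in more than 1 list gave 10 lists. With no filter, 23979 genes were tested and 34 passed (30 higher, 4 lower), all among the 133. RPKM values gave 83 genes (11 lower), 74 of them shared, and no intensity trend gave 74 (64 higher, 10 lower), 63 of them shared. DESeq2 gave 424 (328 higher, 96 lower), among them all 133. In simulated reads, drawn independently by gene with the same dispersion in both groups, it made more false calls than limma. Whether that holds for these libraries, where genes moved together, was not tested. Over the fits with 1 library left out, changed genes ranged from 27 to 183, raised genes from 23 to 149, lowered genes from 4 to 34 and lists from 9 to 13. Camera with an estimated correlation called 0 lists, with 5 at an unadjusted p under 0.05. With the macrophage covariate, limma called 0 genes, 0 raised and 0 lowered, with 874 at an unadjusted p under 0.05 and a smallest adjusted p of 0.35. The standard errors grew, since the score differs between the groups, and some folds were smaller and others larger. With the replicate number as a block, 402 genes (319 higher, 83 lower) and 17 lists passed, 132 of the 133 among them, and so did 9 hepatocyte, 3 erythroid and 2 platelet markers, of which none passed without the block. Deviations of same-numbered libraries from their group means correlated at 0.13, 0.32 and 0.06. Other pairs ran from -0.39 to 0.20 and were mostly negative, the highest being control_iron replicate 3 with high_iron replicate 1. The number was not taken to pair animals, but pairing by number stays open. Depth limits the low genes most: 3 reads are 0.231 CPM in the shallowest library. Leaving out high_iron replicate 3 gave the lowest count, 27, and the cause was not tested, nor were the causes of the other shifts.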

Other observations

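The tests of macrophage RNA as a source and both tests of the macrophage and MHC class II pattern were chosen after the result was seen, and the other tests before. Single genes of several other groups rose on the high-iron diet. Alox12, an arachidonate lipoxygenase on the ferroptosis list, rose from 70.1 ± 19.1 to 179 ± 6.99 CPM (SD, n = 3), 1 of 15 genes tested (list median -0.05, mean 0.11), and missed the threshold without each high_iron library (adjusted p up to 0.10). Of 20 hypoxia-inducible genes Aldoa (0.97 ± 0.13, log2 fold change ± SE) and Egln3 (1.33 ± 0.24) rose, Egln3 in no fit with 1 library left out (adjusted p up to 0.22) and Aldoa not without high_iron replicates 1 and 3 (0.051 and 0.099). Csf1, the growth factor of macrophages, rose by 1.01 ± 0.17, 1 of 20 adhesion and cytokine genes, and missed the threshold without control_iron replicate 2 and without each high_iron library (adjusted p up to 0.18). Rsad2 (0.95 ± 0.15) was the 1 of 33 interferon-stimulated genes, Top2a (0.96 ± 0.18) the 1 of 29 cell cycle genes and Socs3 (0.97 ± 0.16) the 1 of 22 immediate-early genes to rise; Rsad2 missed the threshold without any 1 high_iron library, Socs3 in the 5 fits other than that without control_iron replicate 1, and Top2a in all 6 (adjusted p up to 0.13, 0.18 and 0.22). Adjusted over the list alone, 1 ferroptosis, 3 hypoxia, 2 adhesion, 3 interferon, 8 cell cycle and 2 immediate-early genes rose, and 1 hypoxia and 1 adhesion gene fell. Camera called the interferon and cell cycle lists upward (adjusted p = 2.5e-07 and 1.9e-07; adjusted p = 0.32 and 0.29 with an estimated correlation) and not the other 4. In the same libraries the median log2 fold changes of macrophage, MHC class II and lymphocyte markers were 1.37, 1.75 and 1.17.

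In 13 biology and quality lists no gene passed limma's test: sinusoidal identity, metal response, p53, sterol synthesis, KLF2 and shear stress, lymphatic endothelium, Notch, Wnt, mitochondrial transcripts, iron-sulfur and respiratory chain, extracellular matrix and TGF-beta, integrated stress response and ER chaperones. Of their 202 places, 30 had an unadjusted p under 0.05, 18 higher and 12 lower, edgeR called 0 and DESeq2 8. Fry's test of change in either direction called the sinusoidal identity and integrated stress response lists (adjusted p = 0.0032 and 0.0056), and none of the others. List medians ran from -0.33 (KLF2 and shear stress) to 0.25 (p53), and camera called the p53 list alone (adjusted p = 0.043, adjusted p = 0.32 with an estimated correlation), a call lost without any of the control_iron libraries or high_iron replicate 3 (up to 0.097). Of the lists not called, KLF2 and shear stress passed without control_iron replicate 3 (adjusted p = 0.0089), ER chaperones without high_iron replicate 2 (0.0014), sterol synthesis without high_iron replicate 3 (0.0050) and mitochondrial transcripts without control_iron replicate 1 or high_iron replicate 2 (0.047 and 0.042). Among genes chosen after their values were seen, C5ar1, the receptor for complement C5a, rose from 9.93 ± 2.17 to 45.7 ± 9.87 CPM (SD, n = 3) and Hcst, an adaptor of immune receptors, from 0.559 ± 0.208 to 6.75 ± 1.18 CPM, both in all 6 fits with 1 library left out. Itgal, Fermt3, Ncf1 and Fpr1, known from leukocytes, rose by 1.73, 1.52, 1.40 and 1.63 (log2 fold change), and Pparg by 2.09, and exons of Ncf1 overlap Gtf2ird2 over 11.1%. All 5 passed without control_iron replicate 1 and none without control_iron replicate 3 or high_iron replicate 3 (adjusted p up to 0.21); without high_iron replicate 1 Fermt3 alone passed, without high_iron replicate 2 Itgal alone, and without control_iron replicate 2 Fermt3 and Fpr1. Mafg, a binding partner of NRF2, rose by 0.60, a call lost in each of the 6 fits with 1 library left out (adjusted p up to 0.26).

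Bmp6 and the 16 NRF2 target genes rose together in libraries where macrophage markers were also higher. If macrophage RNA had brought these reads, the genes would follow the macrophage score within groups; their median slope was 0.077 (SD 0.25 over 17 genes), with Gstp1 (0.56), Hmox1 (0.42), Ftl1 (0.42), Blvrb (0.30) and Gstm1 (0.28) highest. With the score as a covariate the median log2 fold change of the 17 genes went from 2.03 to 1.96 and its median SE from 0.17 to 0.35. No call was kept, as the errors about doubled, while 16 of the 17 had an unadjusted p under 0.05 in limma. Some folds were smaller, such as Blvrb (0.99 to 0.58), Gstp1 (2.275 to 1.496), Ftl1 (1.83 to 1.25), Hmox1 (2.97 to 2.38) and Gstm1 (1.68 to 1.29). Those of Txnrd1, Aox1, Gclc, Osgin1, Gsr, G6pdx and Pgd were larger. Hepatocyte RNA was tested in the same way, with a median slope of 0.232 (SD 0.18) and Gstm1 (0.55), Gstp1 (0.51), Ftl1 (0.48), Bmp6 (0.40) and Hmox1 (0.39) highest. Its most abundant markers, Alb and Apoa2, were at 227 and 190.0 CPM on the high-iron diet. Their changes from controls were 51.9 and -14.7 CPM, where Bmp6 and Hmox1 were 639 and 642 CPM higher than in controls. The set was chosen by its calls, which need a small spread within groups, and that also keeps these slopes low. The slopes and the covariate fit, which draws on the same spread, therefore cannot decide on either source for the set. The Alb and Apoa2 levels argue against hepatocyte RNA as the main source of the Bmp6 and Hmox1 rises. A macrophage source stays open, with the highest slopes for Gstp1, Hmox1, Ftl1, Blvrb and Gstm1. Of the 16 macrophage markers Clec4f rose most, by 73.0 CPM, against 639 CPM for Bmp6, 300 CPM for Gclc and 282 CPM for Gclm. Nqo1, Srxn1, Abcc4, Aox1 and G6pdx rose by less than Clec4f. These markers need not be the most abundant macrophage transcripts, so their rises set no bound on other genes. A part from hepatocytes stays open too, among them Gstm1, Gstp1, Ftl1, Bmp6 and Hmox1. A response of endothelial cells to the diet remains a hypothesis.

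Macrophage and MHC class II markers were higher together on the high-iron diet, although the gate excludes cells with CD45, CD64 or MHC class II. A lower share of endothelial cells would raise the markers of all other types alike. The macrophage median (16 genes, without Hmox1 and Slc40a1, which other lists also hold) exceeded the stellate median by 1.08 (SE 0.25). That SE is over marker genes, which move together and are not replicates. The stellate median (0.29) was the lowest of the other cell type lists. Hepatocyte, erythroid, platelet, cholangiocyte and neutrophil medians were also positive (0.57, 0.50, 0.63, 0.65 and 0.37). The comparison therefore cannot decide whether a lower endothelial share added to the rise. The 24 macrophage and MHC class II markers also moved together within groups, as macrophages or their RNA in the sorts would make them. Their mean pairwise correlation was 0.64, at percentile 100 of 10000 random lists matched on expression (95th percentile 0.067). Lists that mark no cell type also moved together, with camera's estimated correlation at 0.82 for mitochondrial transcripts and 0.54 for ER chaperones. Such co-movement cannot tell macrophages or their RNA from expression by the endothelial cells themselves. Their most abundant markers were Fcer1g (330 CPM on the high-iron diet, log2 fold change -0.21), Cd74 (246 CPM) and Clec4f (94.7 CPM). A lower share of endothelial cells, macrophages passing the gate, their RNA or fragments bound to sorted cells, and expression by the endothelial cells themselves stay open. The last was not tested.

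The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Every other split mixes the diets within its groups, so genes that differ between the diets gain spread there. A low count in those splits can come from that alone. The diets gave 133 genes in limma (1572 at an unadjusted p under 0.05) against 0 in the highest other split (up to 1463 at an unadjusted p under 0.05), 108 raised against 0 and 25 lowered against 0, each a result as large in 1 of the 10 splits, and 11 called lists against 13, with 5 of the 10 splits giving as many.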
